A study of Mus musculus with 6 samples.

How the data were processed

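Gene expression was measured in 6 libraries of AML12 cells, 3 labelled sh-NC and 3 labelled sh-1 in the cell line field, which alone defined the groups. The titles of the control libraries name only the cell line, and if those cells carried no hairpin, every fold change would include the effects of transduction and selection. Messenger RNA was enriched with oligo(dT) beads, fragmented and made into cDNA libraries, per the labels' protocols. HISAT2, StringTie and the genome build GRCm38 are named in the submitters' processing notes, and their versions and the way reads were assigned to genes are not given in the sources used here. One deposited table covers the whole series. It holds whole-number counts per gene and library, which the authors did not normalise, per the file headers and the values. It also holds FPKM values per gene and library, scaled by the authors for transcript length and depth, per the file headers. The fold changes (log2) and adjusted p-values of the authors' own DESeq2 comparison of A against B are deposited in the same table, per the file headers, but the samples behind A and B are not given in the sources used here. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. No label gives a batch or a date.

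The table has 26369 rows, of which 26359 with a gene or locus identifier were used, 22036 with Ensembl mouse identifiers and 4323 loci added by the authors' assembly. In GENCODE M21, which is on GRCm38, 22022 of the Ensembl identifiers were found and gave coordinates and exons. Symbols that a spreadsheet had turned into dates (27) were restored from the identifiers. Depth was 36997329 to 51334798 counts per library, the 10 most abundant genes took 7.97 to 9.91% of the counts, and mitochondrially encoded genes took 2.10 to 3.05%.

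Counts were analysed in R 4.3.3 with edgeR 4.0.16, keeping genes by filterByExpr, scaling by TMM and fitting the group alone with robust quasi-likelihood dispersion (glmQLFit and glmQLFTest). P-values were two-sided and adjusted by Benjamini-Hochberg over all 13197 genes tested, with a threshold of 0.05. Counts of genes are also given with an absolute log2 fold change of at least 1. CPM values are scaled by TMM, and errors are the SD over the 3 libraries of a group. SE of a log2 fold change was derived from the F statistic. Gene lists and KEGG pathways of the table's annotation with 15 to 300 tested genes were tested with camera (limma 3.58.1, preset correlation 0.01, log2 CPM), adjusted over the 26 lists and over the 293 pathways, with all tested genes as background, and again with the correlation estimated per set. With an estimated correlation camera refers each statistic to the residual degrees of freedom of the 6 libraries and not to the number of genes. Few sets can then pass whatever their correlation, so a call lost in that setting is no clear evidence against the set. Each member of a list was also adjusted over the list alone. The tests, the 26 lists and the rule for named genes were fixed before the data were examined. The rule takes the TM9SF genes, the 12 largest rises and the 12 largest falls among genes with an adjusted p under 0.05, a mean log2 CPM of at least 3 and groups that do not overlap, without unnamed gene models and pseudogenes, and from each list up to 4 members past the threshold with the smallest adjusted p. It gave 121 genes, of which the text names a part, and 1 of them is not reported here.

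GC content and length were taken from the longest protein-coding transcript of each gene in GENCODE M21, with 11986 of the tested genes (90.8%) covered. To remove their trend, each library's deviation from the gene mean was fitted with natural splines of GC content (5 degrees of freedom) and log2 length (4 degrees of freedom), and the fit entered edgeR as an offset. This correction was chosen after seeing the data. It centres each library on the average gene of a given GC content and length, so a true change shared by such genes is removed as well.

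On simulated counts for this comparison (11986 genes, real means, library sizes and dispersions), 74 of 100 genes changed 2-fold and 58 of 100 changed 1.5-fold were recovered, and 14 unchanged genes were called. With a GC trend added to the sh-1 libraries, 4541 unchanged genes were called without the correction and 9 with it, and 82 of the 100 genes changed 2-fold were then recovered. Of 20 simulated gene sets, camera called all 5 that were shifted and 0 of the other 15. The simulated genes were drawn independently, whereas correlations estimated in the real lists reached 0.66. Far fewer genes were changed than in the data, and the added trend was linear in GC content. It was also less steep than the difference between the real groups, the same in every sh-1 library and without a part for length. The simulation therefore does not show how camera or the correction performs under these conditions.

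Alternatives fixed in advance were scaling by RLE (DESeq2's median ratios), upper quartile or total count, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), a block for the title number, camera with an estimated correlation and leaving out each library in turn. Added after seeing the data were the GC and length correction, the same with the block, annotated genes only and genes with a GENCODE transcript. Summaries were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6, and plots with matplotlib 3.10.9. The mass spectrometry, the mouse experiments and the overexpressing cells that the series describes were not analysed here.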

Results

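The transcriptome of AML12 cells, a non-tumorigenic mouse hepatocyte line, was measured by RNA sequencing of poly(A) mRNA in 6 libraries. The series addresses the role of TM9SF1, a multi-pass protein of endosomal and Golgi membranes, in liver ischemia-reperfusion injury and autophagy, and it describes AML12 lines with stable knockdown of the gene. According to the cell line label, 3 libraries are sh-NC and 3 are sh-1, names that read as a control hairpin and a knockdown hairpin. The titles of the sh-1 libraries carry the name Sh-2, and those of the control libraries carry only the name of the line, so the groups follow the cell line label, and it stays uncertain whether the control cells carried a hairpin. Total counts were 41073857, 39462554 and 51334798 in the sh-NC libraries and 41506383, 40945674 and 36997329 in the sh-1 libraries. The single comparison, sh-1 against sh-NC, asks which transcripts differ between these groups. Replicates of a group differed by far more than sampling noise, with a chi-square per degree of freedom between 14.6 and 53.3 over the 6 pairs, and every library was kept as its own replicate.

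Tm9sf1 mRNA was modestly lower in the sh-1 libraries, and Tm9sf4 was lower by a larger factor. Tm9sf1 lies on chromosome 14 from 55635965 to 55643806 (GRCm38, protein coding). It measured 47.2, 53.4 and 45.8 CPM (counts scaled to 1e6 per library) in the sh-NC libraries and 35.3, 36.8 and 36.5 CPM in the sh-1 libraries. Its mean fell from 48.8 ± 4.03 to 36.2 ± 0.783 CPM (SD, n = 3 each), a ratio of 0.743 with a log2 fold change of -0.43 (SE 0.10, edgeR adjusted p = 0.00186). Once each library's trend along transcript GC content and length was removed, the log2 fold change of Tm9sf1 was -0.09 (SE 0.09, edgeR adjusted p = 0.37) and no longer passed the threshold. Tm9sf4, on chromosome 2 from 153161303 to 153210466, fell from 129 ± 4.78 to 63.4 ± 3.76 CPM (log2 fold change -1.02, SE 0.08, edgeR adjusted p = 4.72e-07), and it stayed lower after the same correction (-0.87, edgeR adjusted p = 1.29e-07). Tm9sf3 rose from 235 to 351 CPM (0.58, SE 0.09, edgeR adjusted p = 0.000117). Tm9sf2 rose from 95.1 ± 12.1 to 117 ± 2.65 CPM (0.30, SE 0.10, edgeR adjusted p = 0.0147), but this call was lost without sh-NC replicate 2 (0.23, edgeR adjusted p = 0.0823) and without sh-NC replicate 3 (0.28, edgeR adjusted p = 0.0563). The rises of Tm9sf2 and Tm9sf3 turned into falls after the correction for GC content and length, to -0.45 and -0.58. Exons of Tm9sf1 overlap those of Gm49378 on the same strand, which measured 0.676 CPM in sh-NC and 0.416 CPM in sh-1.

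**Figure D1:**
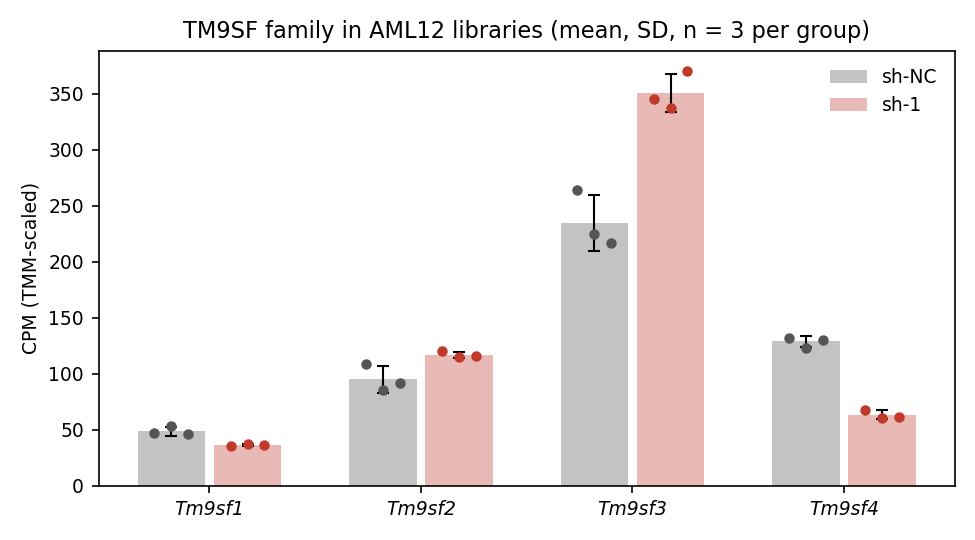
CPM of the 4 TM9SF genes in each library, with dots for single libraries, bars for the group mean and error bars for the SD (n = 3 per group). Tm9sf4 goes from 129 CPM in sh-NC to 63.4 CPM in sh-1, and Tm9sf1 from 48.8 to 36.2 CPM. The rises of Tm9sf2 and Tm9sf3 turned into falls after the correction for GC content and length.

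Differences between the groups extended over most of the measured transcriptome. Of 13197 genes tested, 8648 (65.5%) differed at an edgeR adjusted p under 0.05, with 4395 higher and 4253 lower in sh-1. At least a 2-fold change was reached by 3921 of them, 2262 higher and 1659 lower. The groups did not overlap in 9278 genes (70.3%), where chance gives 10% for 3 libraries against 3. The first principal component carried 78.2% of the variance and separated the groups, and the second carried 6.4%. The biological coefficient of variation was 0.155. Among the changed genes, 8067 were annotated and 581 were loci that the authors' assembly added to the annotation.

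Fold changes followed the GC content of the transcripts. In the tenth of genes with the lowest GC content (31.9 to 41.8%) the median log2 fold change was 1.04, and 69.1% of these genes were higher in sh-1. In the tenth with the highest GC content (58.2 to 74.2%) the median was -0.55, and 55.9% were lower. Across 11986 genes, which are not independent replicates, Spearman's rho between GC content and log2 fold change was -0.50. As deviations from each gene's mean over all libraries, slopes were 0.29, 0.52 and 0.47 log2 units per 10 percentage points of GC in sh-NC. In sh-1 they were -0.29, -0.46 and -0.53. Such deviations cancel over the libraries, so the opposite signs cannot show which group carries the trend. The 13 mitochondrially encoded genes, with a median GC content of 37.1%, had a median log2 fold change of -0.18 (SD 0.49 across genes), against 1.07 in the 939 nuclear genes up to their highest GC content of 41.1%. After the trend along GC content and length was removed from each library, 8078 of 11986 genes passed the threshold, compared with 8086 of the same genes before. Of these genes 2862 were called higher and 3009 lower both before and after, and 376 were called in opposite directions. For this reason the number of members that kept their call after the correction is given with the gene lists below.

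**Figure D2:**
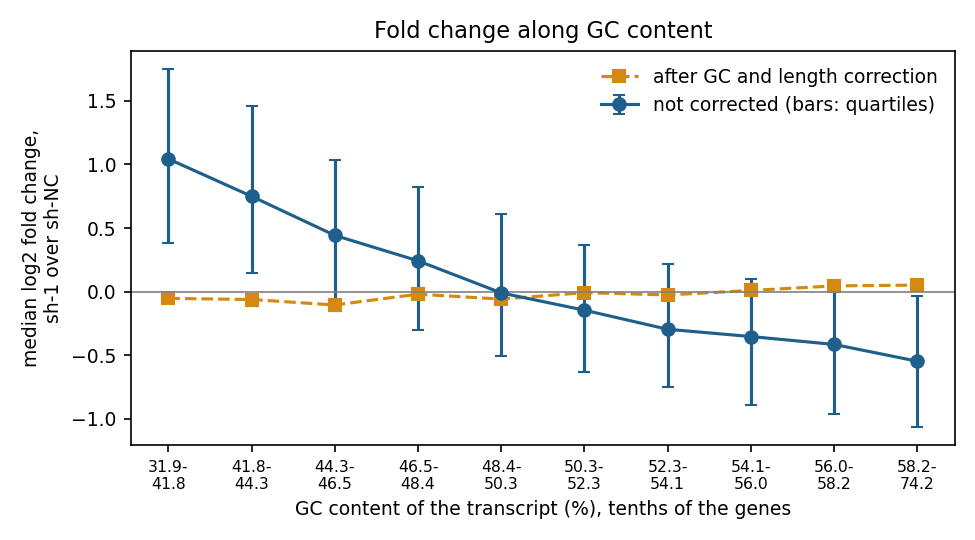
Median log2 fold change (sh-1 over sh-NC) in 10 equal groups of 11986 genes ordered by the GC content of the longest coding transcript, before correction (circles, bars for quartiles) and after removal of each library's trend (squares). The median goes from 1.04 in the group of lowest GC content to -0.55 in the group of highest GC content, and lies near 0 throughout after the correction.

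The strongest rises included secreted inflammatory and matricellular proteins. Cxcl5, a neutrophil-attracting chemokine on chromosome 5 (90759360 to 90761624), rose from 102 ± 2.34 to 2220 ± 288 CPM (21.7-fold, log2 fold change 4.44, SE 0.12, edgeR adjusted p = 1.27e-09). Spp1, which encodes osteopontin (chromosome 5, 104435118 to 104441050), rose from 148 ± 15.4 to 2120 ± 159 CPM (14.3-fold, log2 fold change 3.84, SE 0.12, edgeR adjusted p = 1.99e-09). The epithelial transcription factor gene Ehf went from 0.422 ± 0.206 to 17.7 ± 5.62 CPM (40.7-fold), Samd9l from 1.88 ± 0.283 to 76.7 ± 23.4 CPM (40.5-fold) and Wisp2 from 0.604 ± 0.199 to 22.0 ± 0.799 CPM (35.8-fold). Nrep, Bicc1, Kcnj16, Ms4a4d, Vnn3, Pola1 and Ncald completed the 12 largest rises, with increases between 13.4-fold for Ncald and 34.3-fold for Nrep. After the correction for GC content and length, all 12 stayed higher, with log2 fold changes between 2.83 for Pola1 and 5.63 for Wisp2.

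The strongest falls included stress-inducible and growth factor-responsive genes. Hspa1b, an inducible heat shock protein gene on chromosome 17 (34956436 to 34959238), fell from 24.7 ± 3.18 to 0.400 ± 0.113 CPM (log2 fold change -5.94, SE 0.23, edgeR adjusted p = 6.04e-09). Its level is uncertain because reads may be shared with the near-identical Hspa1a, and how reads were assigned to genes is not given. Egr1, an immediate early transcription factor gene on chromosome 18 (34859823 to 34864984), fell from 33.2 ± 7.78 to 1.16 ± 0.244 CPM (-4.83, SE 0.23, edgeR adjusted p = 1.37e-08). Dusp5, which encodes a phosphatase of ERK, fell from 180 ± 13.0 to 12.3 ± 1.90 CPM (-3.86). Atf3, a stress-induced transcription factor gene, fell from 82.9 ± 2.55 to 7.22 ± 1.98 CPM (-3.52), and the AP-1 gene Fosl1 from 395 ± 12.6 to 43.5 ± 13.5 CPM (-3.18). The abundant Gprc5a fell from 1100 ± 53.3 to 121 ± 29.9 CPM (-3.18). Tmem179, Map3k6, Gpat3, Cenpa, Itgb7 and H2-DMa were the others of the 12 largest falls, with log2 fold changes from -4.77 for Tmem179 to -2.86 for H2-DMa. After the correction all 12 stayed lower, between -5.39 for Hspa1b and -2.46 for H2-DMa.

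Genes of the autophagy machinery, which the series centres on, changed in both directions with more falls than rises. Of 40 core autophagy genes tested, 18 were lower and 10 higher in sh-1, and 17 and 5 of these kept their call after the correction for GC content. Wipi2, which binds phosphatidylinositol 3-phosphate at the forming autophagosome, fell from 341 ± 12.7 to 114 ± 11.9 CPM (log2 fold change -1.58, SE 0.09, edgeR adjusted p = 3.68e-08). Gabarapl1, a member of the ATG8 family, fell from 118 ± 10.1 to 40.1 ± 3.14 CPM (-1.56, SE 0.10), Atg16l1 from 87.8 ± 1.16 to 30.1 ± 4.73 CPM (-1.54, SE 0.11) and the initiating kinase gene Ulk1 from 73.1 ± 3.76 to 30.8 ± 1.78 CPM (-1.24, SE 0.09). Outside the rule for named genes, the related kinase gene Ulk2 rose (1.79, SE 0.15, edgeR adjusted p = 6.56e-07, 1.39 after the correction). Of the other ATG8 genes, Map1lc3a, Map1lc3b and Gabarap did not pass. Gabarapl2 was at 0.30 before the correction and -0.26 after it. The list as a whole did not pass the threshold (camera adjusted p = 0.22), although it did so after the correction (camera adjusted p = 0.0169). Among 15 autophagy receptors, 9 were higher and 5 lower, and 4 and 3 kept their call. The mitophagy receptor genes Bnip3l and Fundc1 rose by log2 1.34 and 1.77, while Sqstm1, which encodes p62, fell from 1520 ± 111 to 660 ± 96.2 CPM (-1.21, SE 0.11, edgeR adjusted p = 1.75e-06) and Tollip fell by 0.97 on the log2 scale. Corrected for GC content, Bnip3l, Fundc1 and Ulk1 were at 0.45, 0.67 and -0.78. The receptor list did not pass (camera adjusted p = 0.32).

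Lysosomal, nutrient-sensing and Golgi genes had no common direction. Of 40 lysosome and V-ATPase genes, 13 were higher and 11 lower (7 and 8 kept their call), with Lamp2 and Atp6v1d up by log2 1.90 and 1.19 and Sgsh at -1.07. The rise of Asah1 (0.92) did not pass the threshold after the correction (0.18). Of 29 regulators of mTORC1, AMPK and TFEB, 9 were higher and 11 lower (6 and 8 kept their call). Sesn2, an inhibitor of mTORC1 induced by stress, fell from 170 ± 7.02 to 51.8 ± 3.80 CPM (-1.72, SE 0.09), and Tfe3, Flcn and Stk11 fell by 1.07, 0.95 and 1.05 on the log2 scale. Of 34 genes of Golgi and secretory trafficking, 8 were higher and 13 lower (4 and 11 kept their call), with Tgoln1 and Kdelr3 at -1.54 and -1.36 and Copb1 and Sar1b at 1.98 and 1.36. Corrected for GC content, Lamp2, Atp6v1d and Sgsh were at 0.83, 0.35 and -0.65, Tfe3, Flcn and Stk11 at -0.56, -0.57 and -0.44, and Copb1 and Sar1b at 1.15 and 0.49. None of these 3 lists passed (camera adjusted p = 0.813, 0.813 and 0.459). In the lysosomal list the median was -0.06 while the mean was 0.08 and the test pointed up, and in the mTORC1 list the median was -0.04 and the test pointed down while the mean was 0.03. In the TM9SF family 2 genes were higher and 2 lower (0 and 1 kept their call, camera adjusted p = 0.813).

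Immediate early genes and genes of the unfolded protein and integrated stress responses were lower in sh-1. Of 23 immediate early genes 20 were lower and 1 was higher, and 18 of the 20 stayed lower after the correction for GC content. Besides Egr1, Dusp5, Atf3 and Fosl1, Dusp1 fell from 22.7 ± 1.75 to 4.74 ± 0.457 CPM (log2 fold change -2.26, SE 0.15, edgeR adjusted p = 9.85e-08). The median of the list was -1.27 (camera adjusted p = 1.61e-05, but adjusted p = 0.532 with an estimated correlation). In the list of the unfolded protein and integrated stress responses, 22 of 29 genes were lower and 4 higher, and 18 of the 22 stayed lower after the correction. Ppp1r15a, which encodes the stress-induced eIF2α phosphatase subunit GADD34, fell from 101 ± 5.79 to 14.2 ± 0.738 CPM (-2.82, SE 0.10, edgeR adjusted p = 3.77e-09). Hyou1, an endoplasmic reticulum chaperone gene, fell from 319 ± 7.37 to 88.9 ± 1.49 CPM (-1.84, SE 0.08, edgeR adjusted p = 6.29e-09). The list had a median of -0.82 (camera adjusted p = 0.000122, but adjusted p = 0.532 with an estimated correlation). Cytosolic ribosomal protein genes were lower in 26 of 34 cases and higher in 1, and 21 of the 26 stayed lower after the correction. Rps18 and Rps2 fell by 1.08 and 0.96 on the log2 scale (Rps2 was at -0.58 after the correction), and the median was -0.54 (camera adjusted p = 0.001, but adjusted p = 0.691 with an estimated correlation). Ribosomal protein genes took 10 to 12.13% of the counts in sh-NC and 8.88 to 9.24% in sh-1.

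Genes of cholesterol synthesis rose together. Of 24 genes of this pathway and other SREBP2 targets, 19 were higher and 3 lower, and 18 of the 19 stayed higher after the correction for GC content. Nsdhl rose from 49.7 ± 4.18 to 244 ± 21.3 CPM (log2 fold change 2.29, SE 0.10, edgeR adjusted p = 7.63e-09), and Cyp51, Fdft1 and Lss, which encode further enzymes of the sterol pathway, rose by 1.84, 1.71 and 1.64. The median of the list was 1.05 (camera adjusted p = 0.000767, but adjusted p = 0.317 with an estimated correlation). The estimated correlation was -0.02, below the preset 0.01, so correlation among the members does not account for this loss. Fatty acid synthesis and storage genes were higher in 12 of 21 cases and lower in 5 (12 and 4 kept their call), with rises of Fads1 (1.41), Scd2 (1.73), Acaca (1.74) and Elovl6 (3.21). The list did not pass before the correction (camera adjusted p = 0.22) and passed after it (camera adjusted p = 0.0225). Of 20 fatty acid oxidation genes 9 were higher and 3 lower (7 and 3 kept their call, camera adjusted p = 0.22). In that list Angptl4, an inhibitor of lipoprotein lipase, fell from 159 ± 3.19 to 35.0 ± 0.163 CPM (-2.18, SE 0.08) and Etfdh rose by 1.34. Among 28 glycolysis and hypoxia genes 15 were higher and 5 lower (14 and 5 kept their call), with Hif1a from 19.3 ± 3.08 to 109 ± 11.0 CPM (2.50, SE 0.13) and Pgk1 from 1750 ± 27.7 to 5150 ± 531 CPM (1.56, SE 0.11), whereas P4ha1 fell by 1.29 on the log2 scale. The corrected value of Hif1a was 1.52. This list passed only after the correction (camera adjusted p = 0.217 before and 0.0109 after). Nuclear oxidative phosphorylation genes were split, with 7 higher and 11 lower of 29 (3 and 8 kept their call, camera adjusted p = 0.696). Of 13 mitochondrially encoded genes 3 were higher and 5 lower (0 and 5 kept their call, camera adjusted p = 0.696), with mt-Nd2 and mt-Nd5 at -0.67 and -0.69. The correction takes the trend of nuclear genes (1.21 at the GC content of this list) from genes that did not follow it, so the fall of all 13 after it (camera adjusted p = 0.00013, mt-Nd1 from 0.90 to -0.32, mt-Nd2 and mt-Nd5 to -1.91 and -1.86) follows from its construction.

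Genes of the inflammatory list rose more often than they fell, and cell death genes moved both ways. In the list of NF-kB targets and inflammatory cytokines 16 of 26 genes were higher and 8 lower, and 15 and 6 kept their call after the correction for GC content (camera adjusted p = 0.112). The KEGG pathways of NF-kappa B signaling (29 higher and 28 lower of 75) and TNF signaling (36 and 37 of 94) were balanced and did not pass (camera adjusted p = 0.945 and 0.92). Members of the list named next are all rises. Besides Cxcl5, the chemokine genes Cxcl1 and Ccl2 rose from 39.8 ± 2.86 to 184 ± 11.3 CPM (log2 fold change 2.21, SE 0.09) and from 64.0 ± 8.85 to 304 ± 15.5 CPM (2.25, SE 0.10), and Lcn2, which encodes the acute phase protein lipocalin, rose from 32.8 ± 5.00 to 183 ± 19.0 CPM (2.48, SE 0.12). The interferon response list had 9 higher and 3 lower of 24 genes (8 and 1 kept their call, camera adjusted p = 0.244), among them Ifi27 (1.56) and Eif2ak2, the gene of the double-stranded RNA-activated kinase PKR (2.37). Of 31 NRF2 and antioxidant genes 16 were higher and 12 lower (12 and 7 kept their call, camera adjusted p = 0.44). Mgst1 and Gsta4 rose by 2.71 and 1.65, and Srxn1 and Txnrd1 were at -1.39 and -1.49. Among 28 apoptosis genes and p53 targets 9 were higher and 16 lower (6 and 15 kept their call, camera adjusted p = 0.226), with Casp8 up by 1.75 and Casp9 and Tnfrsf10b at -1.24 and -1.23. The list of ferroptosis, necroptosis and pyroptosis had 11 higher and 3 lower of 16 genes (7 and 2 kept their call, camera adjusted p = 0.112). Acsl4 and Lpcat3, whose enzymes build polyunsaturated phospholipids, rose by 2.46 and 1.63, the transferrin receptor gene Tfrc rose from 24.1 ± 7.16 to 153 ± 10.4 CPM (2.66, SE 0.17), and the cystine transporter subunit gene Slc3a2 fell from 2120 ± 116 to 366 ± 44.5 CPM (-2.53, SE 0.11). Ccl2, Acsl4 and Tfrc were at 1.40, 1.31 and 1.60 after the correction.

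Hepatocyte genes changed in both directions, and so did markers of other liver cells. Of 31 hepatocyte identity genes 6 were higher and 14 lower, and 5 and 9 kept their call after the correction for GC content (camera adjusted p = 0.22). The median log2 fold change of the list was -0.795, so the rises named next are not typical of it. Hnf4a, a central transcription factor of hepatocytes, rose from 150 ± 5.24 to 337 ± 25.5 CPM (log2 fold change 1.17, SE 0.08, edgeR adjusted p = 1.66e-07), and the bile acid receptor gene Nr1h4 rose from 8.17 ± 0.0583 to 45.6 ± 1.47 CPM (2.48, SE 0.11). Apob rose by 2.53, and Rbp4, whose product carries retinol in plasma, fell from 405 ± 55.0 to 223 ± 8.10 CPM (-0.86, SE 0.10), with corrected values of 1.53 and -0.49. Of 17 tested genes of drug and bile acid metabolism 6 were higher and 6 lower, and all of these kept their call (camera adjusted p = 0.904). Abcc3 and Aldh3a1 rose by 1.16 and 1.92 and Por and Abcc4 were at -1.12 and -0.89, Por at -0.56 after the correction. The median of that list was -0.16, while its mean was 0.61 and its test pointed up. Among 21 extracellular matrix and mesenchymal genes 11 were higher and 5 lower (10 and 3 kept their call), with Thbs1 from 11.2 ± 2.27 to 62.7 ± 6.89 CPM (2.49, SE 0.15) and Fn1 from 78.9 ± 3.81 to 297 ± 51.1 CPM (1.91, SE 0.12), and the list passed only after the correction (camera adjusted p = 0.226 before and 0.0117 after). Cholangiocyte and epithelial genes were higher in 5 and lower in 2 of 10 cases (4 and 2 kept their call, camera adjusted p = 0.226), where Spp1 and Cd24a rose and Sox9 fell by 1.62 on the log2 scale. Only 7 of 20 macrophage, leukocyte and endothelial markers were tested, 2 higher and 3 lower (2 and 2 kept their call, camera adjusted p = 0.698), and Cd68 was at 4.82 ± 0.292 CPM in sh-NC and 0.844 ± 0.257 CPM in sh-1. Cell cycle genes were higher in 19 and lower in 11 of 34 cases (18 and 11 kept their call, camera adjusted p = 0.305). Mcm6 and Rrm2 rose by 1.75 and 1.78, and Aurka and Cdc20 were lower (log2 fold changes -2.23 and -2.01).

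**Figure D3:**
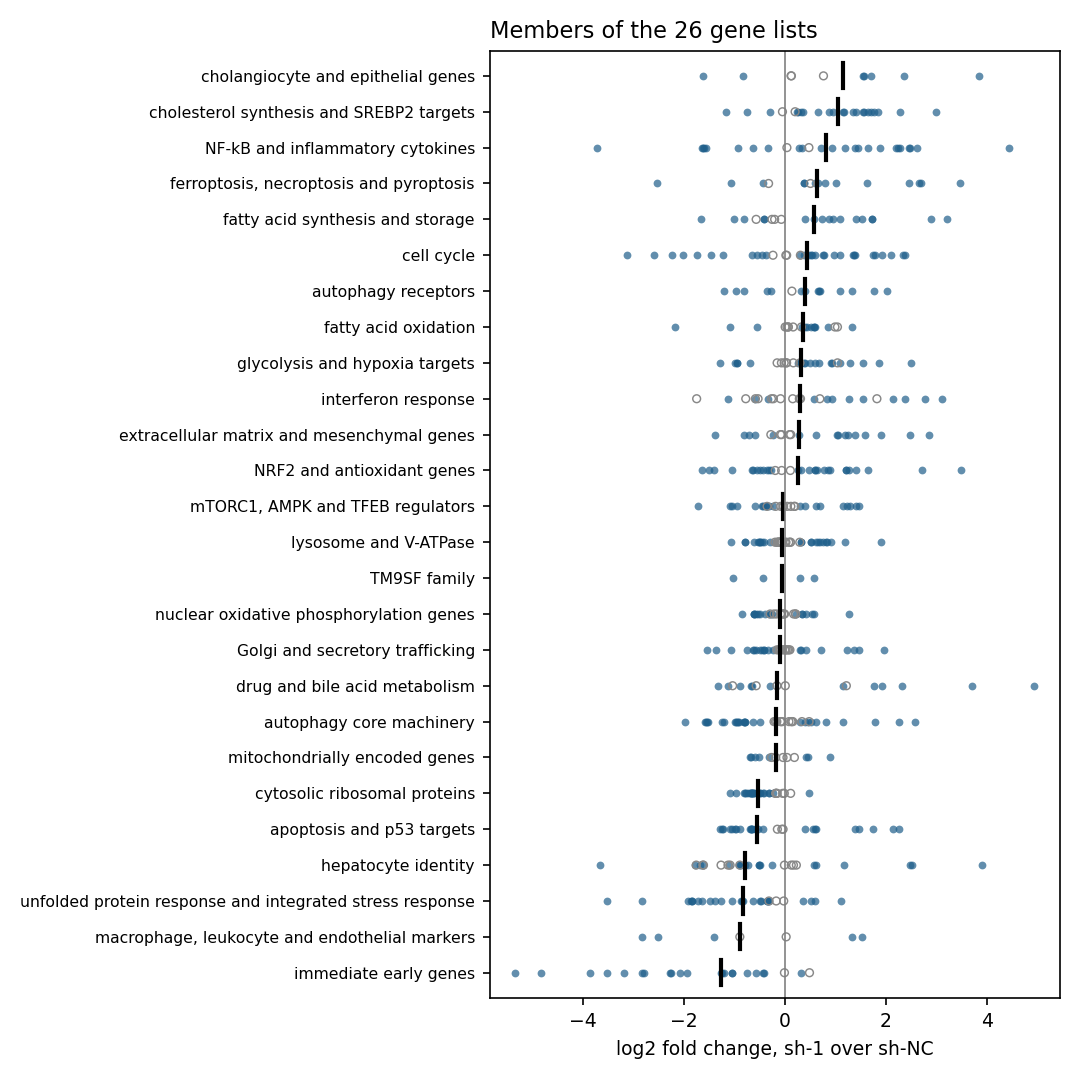
Log2 fold change (sh-1 over sh-NC) of each tested member of the 26 gene lists, with filled dots for genes past an edgeR adjusted p of 0.05, open dots for the others and a black bar for the median of the list. The medians run from -1.27 in immediate early genes to 1.16 in cholangiocyte and epithelial genes. The values are not corrected for GC content.

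Adjusted over the list alone, the counts in these 26 lists were the same except for core autophagy genes (11 higher and 18 lower), regulators of mTORC1, AMPK and TFEB (10 and 11) and fatty acid synthesis and storage (12 and 6). Of 293 KEGG pathways in the annotation of the deposited table, 15 were higher and 2 lower in sh-1 by camera. The lowest adjusted p was shared by drug metabolism and metabolism of xenobiotics by cytochrome P450 (29 and 28 of 45 genes higher, camera adjusted p = 0.000882 for each), where Mgst1, Gsta4 and Aldh3a1 were among the members. Fatty acid degradation (24 of 41 higher), degradation of branched-chain amino acids (30 of 52), peroxisome (42 of 84), homologous recombination (29 of 48) and mismatch repair (16 of 24) were also higher, but homologous recombination did not pass after the correction for GC content (camera adjusted p = 0.1). Ribosome (87 of 155 lower) and RNA polymerase (17 of 30 lower) were the lower pathways. With an estimated correlation none of the 293 pathways passed, the adjusted p of each called pathway then being 0.986. Pathways far from a call, such as animal autophagy and lysosome, had the same value, so it does not separate the called ones from others. Of the 17 calls 14 were kept among the 11986 genes with GC content before any correction and 13 after it. The KEGG pathways of animal autophagy (45 higher and 48 lower of 134) and lysosome (44 and 44 of 136) did not pass (camera adjusted p = 0.945 and 0.941).

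The strand setting of the counting is not given in the sources used here, so reads of genes with overlapping exons cannot be told apart. Among the genes named above with values, exons of Dusp5, Fosl1, Dusp1, Ppp1r15a, Sqstm1, Gabarapl1, Cyp51, Fdft1, Lss, Lpcat3, Cdc20, Casp9, Fn1, Thbs1, H2-DMa, Bicc1, Kdelr3, Stk11, Sgsh, Tgoln1, Etfdh, Eif2ak2, Elovl6, mt-Nd5 and Rps18 overlap exons of an annotated gene on the opposite strand. Exons of Spp1, Scd2, mt-Nd1 and mt-Nd2 overlap another gene on the same strand, and those of Hif1a, Gpat3, Ncald, Rps2 and Tm9sf1 overlap genes on both strands.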

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

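The tests of explanations in this part were chosen after the results were seen. The authors' deposited table gives 3250 genes with an adjusted p under 0.05 for its comparison of A against B, a signal in columns that no comparison above uses, 1846 higher and 1404 lower. Of the 3249 also tested here, 3226 had the same sign as sh-1 against sh-NC and 3037 of those were called here as well. In the authors' deposited table Tm9sf1 has a log2 fold change of -0.56 (adjusted p = 0.000384) and Tm9sf4 one of -0.62 (adjusted p = 0.0469).

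The deposited fold changes of A against B do not equal those of the 6 libraries. Their Pearson r with the fold changes computed here was 0.727 across 11443 genes. Over 500 ordered pairs of disjoint subsets of the 6 libraries the highest r was 0.785. It came from subsets that mix the groups, sh-NC replicate 1 with sh-1 replicates 2 and 3 against sh-NC replicates 2 and 3, with or without sh-1 replicate 1. In the 1484 genes with a mean log2 CPM of at least 7, where shrinkage should matter least, the highest r of any pair was 0.919. This argues against another grouping of these libraries. Fold changes in the authors' deposited table follow GC content more closely (Spearman's rho -0.712 across genes) than those computed here on the same genes (-0.516). Which samples stand behind A and B, and whether they include libraries not used here, stays open.

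Fold changes follow GC content, and a smooth trend along GC content and length as the whole cause of the changed genes is argued against by 5871 genes called in the same direction before and after its removal, of 8086 called before. Amplification or sequencing that acted on every fragment by its GC content would have raised the mitochondrially encoded genes by log2 1.21, and their median was -0.179 (SD 0.487), while 35 abundant nuclear genes of that GC range had a median of 0.701. Between the groups this argues against such a bias as the source of the trend unless mitochondrial RNA fell at the same time. Within sh-1, however, the mitochondrial shares of counts were 2.10, 2.67 and 3.05% at slopes of -0.286, -0.463 and -0.533, the order such a bias gives. In sh-NC they were 2.78, 2.29 and 2.88% at slopes of 0.285, 0.522 and 0.473, without a steady order. The mitochondrially encoded genes therefore leave such a bias undecided. Cells, RNA or libraries of the groups handled apart cannot be told apart from the hairpin, since no label gives a batch and the slopes of replicates ranged over only 28.9% of the difference between groups, and a real change of many transcripts in sh-1 cells is an untested alternative. For Tm9sf1 the trend fits, as its log2 fold change went from -0.428 (SE 0.097) to -0.089 (SE 0.085), the call ending because the fold shrank and not because the error grew, and 42.8% of 463 genes of like GC content and expression had lower fold changes, so that these libraries show no lowering of Tm9sf1 beyond that of comparable genes.

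Of the immediate early genes 20 of 23, and of the stress response genes 22 of 29, were lower in sh-1, although both list calls are lost with an estimated correlation (camera adjusted p = 0.532 each). The GC and length trend as their whole cause is argued against by 18 of 20 immediate early genes and 18 of 22 genes of the unfolded protein and integrated stress responses that stayed lower after the correction. Of all 3994 genes called lower before it, 3009 stayed lower, so this is not particular to the 2 lists. Their medians shrank from -1.27 to -1.09 and from -0.82 to -0.56. Cells handled or harvested differently between the groups, for example in density, medium change or time to lysis, could lower these genes, which respond within minutes to hours, and 87.0% of the immediate early genes and 75.9% of the stress response genes tested were lower. That explanation cannot be told apart from an effect of the hairpin here, because each group may have been handled as one set and no label records it. A lower stress load in the sh-1 cells is the biological alternative and remains untested.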

How the results depend on the processing

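The correction for GC content and length, its combination with the block, annotated genes only and genes with a GENCODE transcript were chosen after seeing the data, and the other alternatives before. The count of changed genes (8648) stayed between 7366 (the block with the correction) and 8802 under every alternative that left no library out. It lay between 7912 and 8728 when a library was left out. Limma on log2(FPKM + 1), which compresses the change of low genes, gave 2047 genes changed at least 2-fold (1299 higher and 748 lower, against 2262 and 1659). With the correction 1395 genes were at least 2-fold higher and 1295 lower, against 2043 and 1402 of the same 11986 genes without it. The title numbers 2 and 3 occur in both groups, but libraries with the same number did not deviate together (correlations 0.03 and -0.053), so they were not taken as pairs. Numbers 1 and 4 each occur in 1 library, so sh-1 replicate 1 and sh-NC replicate 3 are taken up by their own block terms. Under the block the comparison therefore rests on the libraries numbered 2 and 3 alone. With the replicate block by title number 7465 genes changed (3842 higher and 3623 lower), and 4 of 120 named genes other than Tm9sf1 lost their call (Tm9sf2, Cdh5, Csf1r and mt-Co3). The replicate block together with the correction gave 2576 genes changed at least 2-fold, 1332 of them higher. Apart from the fewer libraries behind the block fits, the cause of these shifts in counts was not tested.

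Tm9sf1 kept its direction and call under all alternatives except the correction (-0.089, adjusted p = 0.37) and its combination with the block (-0.102, adjusted p = 0.375), which remove the trend it follows. Reversed by the correction and by its combination with the block were Tm9sf3 (-0.585 and -0.751), Tm9sf2 (-0.448 and -0.538), Uqcrc2 (-0.114 and -0.168) and mt-Nd1 (-0.315 and -0.368). Exons of Uqcrc2 overlap a gene on the opposite strand. Of the 120 named genes, 114 kept direction and call under the correction, and all kept both under the other scalings, filters and tests with all libraries, 1 being absent under the stricter filter. Leaving out 1 library ended the call of at most 2 of them.

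Of the gene lists, those of autophagy core genes (adjusted p = 0.0169 with the correction and 0.0187 with the replicate block added), fatty acid synthesis (0.0225 and 0.0277), glycolysis (0.0109 and 0.0138), extracellular matrix (0.0117 and 0.0127) and mitochondrially encoded genes (0.00013 and 0.000278) passed the threshold under these alternatives only. For the mitochondrially encoded list, and for mt-Nd1 above, this follows from how the correction is built, since it removes a trend that these genes did not follow. Under the same pair the mTORC1 list (0.895 and 0.832) and the drug and bile acid list (0.94 and 0.974) changed direction without a call. The lysosome list changed direction, without a call, with the replicate block (0.735) and without sh-1 replicate 1 (0.768, range 0.482 to 0.953 over the fits without 1 library), and the mitochondrial list with the replicate block (0.916). With an estimated correlation the calls of immediate early genes (0.532), stress responses (0.532), cholesterol synthesis (0.317) and ribosomal proteins (0.691) were lost, as were all pathways (0 higher and 0 lower). For cholesterol synthesis the estimate (-0.02) lay below the preset 0.01, so a higher correlation does not account for the loss. The few degrees of freedom in that setting make every set less likely to pass. Their share in the other losses was not separated from that of correlation. Lower pathways numbered 1 with the replicate block, 1 with the block and the correction, and 1 to 2 when a library was left out. For the other shifts of lists and pathways the cause was not tested. Alternatives planned for a table without counts did not apply. The calls lost in fits without 1 library were those of Tm9sf2 and of Csf1r and Vwf, which are both of low expression.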

Other observations

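The 5 gene lists and all genes named in the first 2 paragraphs of this part were chosen after their values were seen. Of 27 glutathione S-transferase and aldehyde dehydrogenase genes tested, 19 were higher and 2 lower by edgeR (median log2 fold change 0.88), and 18 of the 19 stayed higher after the correction for GC content. Gsta3 rose by 2.98 (SE 0.26), Aldh6a1 by 1.66 (SE 0.20) and Aldh3b1 by 1.09 (SE 0.10), Aldh6a1 being at 0.86 after the correction. Among 12 genes of the Schlafen family, Samd9l and interferon-inducible GTPases, 7 were higher, 1 lower and 4 not past the threshold. All 7 stayed higher after the correction, when 3 of the 12 were lower, and no test of the list was made. Among the higher genes were Slfn9 (3.51, SE 0.20), Ifi47 (3.57, SE 0.15) and Slfn2 (1.90, SE 0.12).

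Heat shock genes changed in both directions. Of 19 tested, 8 were higher and 9 lower in sh-1, and 6 and 8 of them kept their call after the correction. Bag3 (-1.93, SE 0.08), Dnajb1 (-1.74, SE 0.09) and Hspb8 (-1.62, SE 0.09) fell, while Hsp90aa1 (2.48, SE 0.19), Hspa4l (2.15, SE 0.17) and the mitochondrial chaperone gene Hspd1 (0.85, SE 0.09) rose. Among 24 aminoacyl-tRNA synthetase and amino acid transporter genes 13 were lower and 4 higher, and 10 and 2 kept their call. The amino acid transporter genes Slc7a5 and Slc7a1 were at -1.73 (SE 0.09) and -1.13 (SE 0.10), and the synthetase gene Aars at -0.95 (SE 0.08). After the correction Hspa4l, Hspd1 and Aars were at 0.93, 0.54 and -0.58. Of 12 circadian clock genes 6 were lower and 3 higher, and 5 and 2 kept their call. Per1 and Nr1d1 fell (-2.71, SE 0.13 and -1.83, SE 0.10) and Arntl rose (1.74, SE 0.20). Exons of Aldh6a1, Hspd1, Nr1d1 and Arntl overlap a gene on the opposite strand, and those of Aars and Ifi47 overlap genes on both strands.

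Other splits of the 6 libraries into 3 and 3 were counted for each result. There are 10 such splits, too few for a share under 0.05. The real split gave 8648 changed genes and the highest of the others 0, and for genes changed at least 2-fold these counts were 3921 and 0, so that 1 of the 10 splits gave as many in either case. For KEGG pathways the real split gave 17 calls and the highest other 16, with 1 of the 10 splits reaching the real count. For gene lists it gave 4 calls and the highest other 6, with 6 of the 10 splits giving as many. Each other split mixes both groups on each side, so the group difference widens the spread within sides and holds gene calls down. A part of that difference remains between the sides, so set calls there are not free of it. The counts therefore cannot measure what chance alone would give.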
